A study of Mus musculus with 16 samples.

How the data were processed

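RNA sequencing of mouse cortical tissue was analysed in 16 libraries, made from embryos at E13.5 and from pups at P0, the day of birth. Each stage had 4 control and 4 conditional knockout (cKO) libraries. Per the labels, the cKO animals carried Emx1-Cre and a conditional allele of Bptf, and the controls lacked Cre, so Cre presence and genotype cannot be separated. Libraries were stranded and made from messenger RNA, per the labels' protocols. The labels number the samples but do not say that each came from a separate animal, so p-values measure the spread between these samples.

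The deposited values are estimated counts per transcript, which need not be whole numbers. Per the submitters' processing notes, the tools were Salmon 1.4.0, kallisto 0.44.0 and DESeq2, with the mouse builds mm10 and GRCm38; the role of DESeq2 is not given in the sources used here. Per the file headers, the E13.5 files have the layout of Salmon, with estimated counts, TPM and effective lengths, and the P0 files that of kallisto, with estimated counts and effective lengths. The TPM values deposited for E13.5 were checked for their unit and not used in any test. The annotation release behind the transcripts is not given in the sources used here. Because each stage was quantified by another tool, the stage effect itself is not reported, and each stage kept its own genes and its own estimate of the spread.

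Estimated counts were summed per gene with the GENCODE vM21 annotation of GRCm38 and rounded to whole numbers. The files listed 116546 transcripts at E13.5 and 113193 at P0, which gave 35498 and 35150 genes. Transcripts without a gene name in that annotation held 0.109% to 0.121% of the counts at E13.5 and 0.675% to 0.699% at P0, and stayed out of library sizes and tests. Totals ran from 23092956 to 31797226 counts per library at E13.5 and from 46434601 to 77836210 at P0, so a gene at a given level was measured with less counting error at P0. Reads carry no molecular identifiers, so counting error is a lower limit of the true error. Pairs of libraries of the same group differed by more than sampling noise (chi-square per degree of freedom 5.22 to 27.5 over 24 pairs), so each library counted as 1 sample.

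Genes were tested with edgeR 4.0.16 in R 4.3.3 (filterByExpr at its default minimum count of 10, TMM normalisation, quasi-likelihood fit and F test, Benjamini-Hochberg adjustment, threshold 0.05). CPM values use the TMM-scaled library size, given as mean ± SD over libraries, and log2 fold changes are cKO over control with their standard error (SE). The difference between stages was tested as the interaction of stage and genotype over all 4 groups, on the 14950 genes that passed both filters. Overlap of calls was tested with Fisher's exact test, two-sided, per direction.

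A set of 30 gene lists was fixed before the data were examined, along with the tests, the alternative settings and the rule for named genes. The lists cover subunits of NURF, the chromatin remodelling complex that holds BPTF, and of other ISWI remodelling complexes. They also cover the cell types of the cortex (apical and intermediate progenitors, newborn, upper-layer, deep-layer and subplate neurons, Cajal-Retzius cells). Further lists hold other cell types found in the cortex (interneurons, microglia, endothelial cells and pericytes, astrocytes, oligodendrocyte lineage). Tissues and cells that a dissection can carry along have lists too (ventral forebrain and striatum, hippocampus and cortical hem, thalamus, choroid plexus, meningeal fibroblasts, red blood cells). The others are the cell cycle (S phase, G2 and M phase), p53 targets and cell death, the integrated stress response, the interferon response, immediate early genes, WNT and SHH signalling targets, synapse and neuronal maturation, axon guidance and mitochondrially encoded genes. Some genes stand in more than 1 list. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01 between genes, adjusted over the 30 lists; an estimated correlation per list and the rotation test fry were alternatives. For each list, members passing the test are counted with adjustment over all genes and adjusted over the list alone.

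The rule names Bptf and Emx1; per stage the 8 largest rises and the 8 largest falls among genes past the threshold, with a mean log2 CPM of at least 1, no overlap between the groups and no predicted-model symbol, and leaving out Y-linked genes; per list up to 4 members past the threshold with the smallest p, or up to 2 of highest mean CPM where none passed; and 5 genes per direction for the interaction with the same limits on level and symbol. Any other gene named was chosen after its values were seen.

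Alternatives were DESeq2 size factors, the DESeq2 1.42.0 Wald test, no filter beyond 1 count, offsets for effective transcript length, a fit over all 4 groups, the replicate number as a block at E13.5, and leaving out each library in turn. Length offsets were not applied to the list tests. A covariate of Xist level was planned and not run, because Xist is not among the transcripts used here; the log2 level of the Y-linked gene Ddx3y (CPM plus 0.1) was used in its place, chosen after seeing the data. A count of calls is said to have moved where it changed by more than 1.5 times, and a result without a call in either fit is taken as the same.

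The steps were tested on simulated counts with 200 changed genes, drawn only from genes above a minimum mean level. The recovery rates therefore do not cover genes with low counts. The gene test recovered 78% of genes changed 1.5-fold and 86% of genes changed 2-fold at E13.5, with 3.53% false calls, and 84% and 95% at P0, with 5.29% false calls. The interaction test recovered 82% of 2-fold differences. Genes called in the real data had a median absolute log2 fold change of 0.425 at E13.5 and 0.357 at P0, smaller than both simulated folds. The list test called the raised list at both stages, and with it 1 of 29 unchanged lists. Genes were simulated independently of each other, while members of real lists vary together (estimated correlation 0.87 for meningeal fibroblasts at E13.5). The simulation therefore does not measure false calls of lists at the preset correlation in the real data.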

Results

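The series asks how BPTF, the largest subunit of the nucleosome remodelling factor NURF, contributes to development of the mouse neocortex. Messenger RNA of cortical tissue was sequenced from controls and from animals in which Cre, expressed from the Emx1 locus, recombines Bptf in progenitors of the dorsal telencephalon. There were 4 control and 4 cKO libraries at E13.5, with 23092956 to 31797226 estimated counts each, and 4 control and 4 cKO libraries at P0, with 46434601 to 77836210 each. At E13.5 the 20 most abundant genes held 5.84% to 6.03% of counts in controls and 5.88% to 6.19% in cKO libraries; at P0 they held 7.27% to 7.61% in controls and 6.36% to 6.74% in cKO libraries.

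Bptf transcripts (ENSMUSG00000040481, chromosome 11, 107033081 to 107132127, GRCm38) were lower in cKO tissue at both stages. At E13.5 the mean fell from 226 ± 8.17 to 163 ± 1.03 CPM (SD, n = 4 each), a log2 fold change of -0.47 (SE 0.04; edgeR adjusted p = 0.00018). At P0 it fell from 163 ± 10.5 to 134 ± 13.7 CPM (SD, n = 4 each), a log2 fold change of -0.28 (SE 0.07; edgeR adjusted p = 0.0129). At both stages all 4 cKO libraries lay below all 4 controls. At P0 the margin was narrow, with 153.4 CPM in cKO 7 and 153.7 CPM in control 4. The other P0 cKO libraries measured 124.3 to 134.9 CPM. Gene counts do not resolve the deleted exons, so the remaining signal can hold transcripts from the recombined allele and from cells that never expressed Cre. Emx1, the transcription factor gene whose locus drives Cre (chromosome 6, 85187438 to 85204462), measured 70.5 ± 7.14 and 56.6 ± 4.68 CPM at E13.5, a difference that did not pass the test (log2 fold change -0.32, SE 0.08, edgeR adjusted p = 0.0752). At P0 Emx1 fell from 33.9 ± 0.259 to 17.3 ± 1.48 CPM (log2 fold change -0.98, SE 0.06, edgeR adjusted p = 1.66e-06). Because Cre was present in cKO samples alone, an effect of the Cre allele on its own locus cannot be separated from the loss of BPTF.

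**Figure D1:**
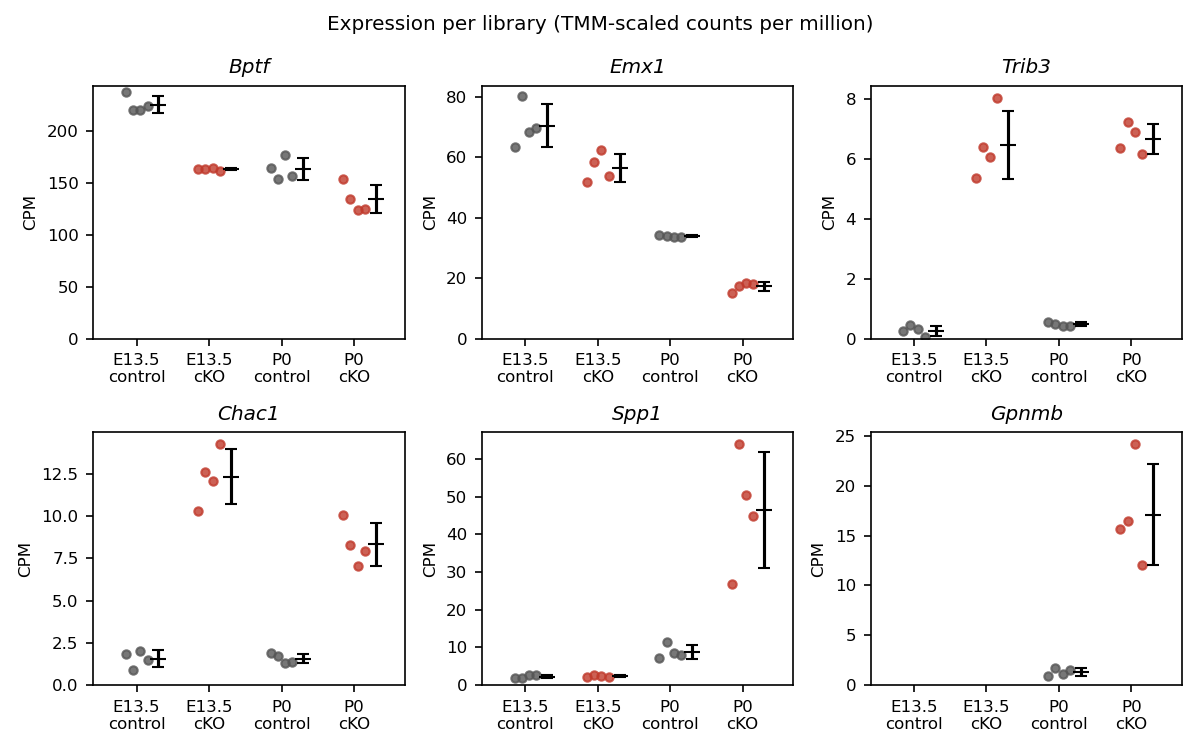
TMM-scaled CPM of 6 genes in each library (points; controls grey, cKO red) by group, with the group mean and SD (n = 4) as black bars. Bptf lies lower in all 4 cKO libraries than in all 4 controls at both stages, Trib3 and Chac1 lie higher, and Gpnmb, which passed the low-count filter only at P0, is drawn there alone. For Bptf at P0, cKO 7 (153.4 CPM) lies just below control 4 (153.7 CPM).

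The first comparison asks which genes differ in cKO cortex at E13.5, during neurogenesis. Genes of the integrated stress response, which the transcription factor ATF4 switches on when translation initiation is restrained, rose together. Of 15 measured members 12 rose and 0 fell (15 rose adjusted over the list alone), with a median log2 fold change of 0.94. Trib3, a pseudokinase gene induced by ATF4, rose from 0.264 ± 0.169 to 6.44 ± 1.14 CPM (SD, n = 4 each; log2 fold change 4.54, SE 0.35). Chac1, which encodes a glutathione-degrading enzyme, rose from 1.55 ± 0.494 to 12.3 ± 1.63 CPM (2.99, SE 0.22). Atf5, a transcription factor gene under the same control, rose from 37.8 ± 3.62 to 144 ± 33.1 CPM (1.93, SE 0.14). Mthfd2, an enzyme of mitochondrial folate metabolism, rose from 20.9 ± 1.54 to 40.1 ± 3.06 CPM (0.94, SE 0.07). The edgeR adjusted p was 0.000132 for Trib3 and Mthfd2 and 0.000118 for Chac1 and Atf5. The list passed camera (adjusted p = 1.11e-86) and passed again with an estimated correlation (adjusted p = 0.00214 with an estimated correlation).

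Over the transcriptome at E13.5, 287 of 15165 tested genes passed edgeR's quasi-likelihood test, 132 higher and 155 lower in cKO tissue, and 2422 had an unadjusted p under the threshold. Among them 24 rose and 7 fell by more than 2-fold. The groups did not overlap for 1600 genes (10.6%, against 2.86% by chance). Outside the stress list, Trim66, a chromatin reader of the tripartite motif family, rose from 0.972 ± 0.15 to 15 ± 4.2 CPM (log2 fold change 3.95, SE 0.23, edgeR adjusted p = 4.22e-05). The cationic amino acid transporter gene Slc7a3 rose from 1.31 ± 0.195 to 14.3 ± 3.37 CPM (3.45, SE 0.20, edgeR adjusted p = 4.22e-05). Eif4ebp1, which encodes an inhibitor of cap-dependent translation, rose by a log2 fold change of 2.06 (edgeR adjusted p = 0.000118). The collagen receptor gene Ddr2 rose by 2.02 and the secreted glycoprotein gene Stc2 by 1.73 (edgeR adjusted p = 0.0115 and 0.000438). Among the genes that fell were Ppp1r14a, an inhibitor of myosin phosphatase (log2 fold change -1.61, edgeR adjusted p = 0.000803), and Ahrr, the repressor of the aryl hydrocarbon receptor (-1.38, edgeR adjusted p = 0.00504). The zinc finger gene Zkscan4 (-1.06), the apical junction gene Ajm1 (-1.01) and the transmembrane protein gene Tmem44 (-0.89) also fell (edgeR adjusted p = 0.00204, 0.00237 and 0.0105). So did the clustered protocadherin gene Pcdhb19 (-0.94), Rasgrf1, a Ras exchange factor (-0.90), and the zinc finger gene Zfp820 (-0.89; edgeR adjusted p = 0.0329, 0.031 and 0.0492). Pcdhb19 and Zfp820 share sequence with neighbouring family members, so their values are less certain. The number of calls moved with the fit, to 157 with transcript-length offsets, 181 with a Ddx3y covariate, 159 with a replicate block, 579 with all 4 groups in 1 fit and 695 with DESeq2, and it was 156, 160, 160, 168, 181 and 187 without control 3, cKO 2, cKO 4, control 4, control 1 and control 2. The calls of Pcdhb19, Rasgrf1, Zfp820, Smarca1, Wnt7b, Slc17a6 and Pmaip1 were lost under 8, 6, 9, 10, 8, 10 and 7 of 15 alternatives, and that of Hmgxb4 with length offsets alone (edgeR adjusted p = 0.0862).

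Intermediate progenitor, newborn neuron and upper-layer lists had small negative medians at E13.5, and their camera calls were lost with an estimated correlation. Of 13 intermediate progenitor genes 0 passed over all genes and 7 fell adjusted over the list alone. Their median log2 fold change was -0.16 (camera adjusted p = 2.24e-06; adjusted p = 0.525 with an estimated correlation). Eomes, the T-box factor that marks these cells, measured 235 ± 14.2 CPM in controls and 208 ± 12 in cKO libraries (log2 fold change -0.17, edgeR adjusted p = 0.158). The zinc finger gene Insm1 measured 217 and 200 CPM (-0.12). Of 16 genes of newborn and migrating neurons 2 fell (3 adjusted over the list alone), the neurogenic factor gene Neurod1 (-0.41, edgeR adjusted p = 0.00789) and the semaphorin receptor gene Nrp1 (-0.49, edgeR adjusted p = 0.00307). Their median was -0.10 (camera adjusted p = 0.000101; adjusted p = 0.672 with an estimated correlation). Of 17 upper-layer genes 0 passed over all genes or adjusted over the list alone, with Pou3f3 at -0.13 and Lhx2 at -0.16. Their median was -0.09 (camera adjusted p = 0.0266; adjusted p = 0.866 with an estimated correlation). That call was lost without control 3 (0.107) or cKO 1 (0.0668). Among the NURF and ISWI subunits, Bptf and Smarca1, an ISWI ATPase (-0.29, edgeR adjusted p = 0.0445), fell and Hmgxb4, a BPTF partner, rose (0.43, edgeR adjusted p = 0.00154). The same 3 of 14 passed adjusted over the list alone (median -0.08, camera adjusted p = 0.0266; adjusted p = 0.866 with an estimated correlation; 0.244 without cKO 4). Of 20 axon guidance genes 0 passed over all genes or adjusted over the list alone, with the adhesion gene Cntn2 at -0.16 and the ephrin receptor gene Epha4 at -0.02. Their median was again -0.09 (camera adjusted p = 0.0266; adjusted p = 0.866 with an estimated correlation). Without control 1 or cKO 2 the camera adjusted p was 0.119 and 0.0987. Among synaptic genes 1 of 20, the vesicular glutamate transporter gene Slc17a6, fell (-0.29, edgeR adjusted p = 0.0253), and 2 fell adjusted over the list alone. Their median was -0.06 (camera adjusted p = 0.0454; adjusted p = 0.866 with an estimated correlation). Without control 1, control 3, cKO 1 or cKO 2 the camera adjusted p was 0.553, 0.135, 0.0702 and 0.584. The median turned to 0.04 without control 1 and 0.01 without cKO 2.

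Choroid plexus and microglia lists passed camera at E13.5 at the preset correlation alone, and both lay lowest in control 1. Of 13 choroid plexus genes 0 passed over all genes or adjusted over the list alone. Their median log2 fold change was 0.79 (camera adjusted p = 0.000344; adjusted p = 0.866 with an estimated correlation). Ttr, the transthyretin gene of that epithelium, measured 156 ± 132 CPM in controls and 315 ± 122 in cKO libraries (edgeR adjusted p = 0.549), and Clic6 12.9 ± 9.38 and 23.9 ± 10.7. Of 16 microglia genes 0 passed over all genes or adjusted over the list alone, with Csf1r at 0.18. Their median was 0.24 (camera adjusted p = 0.0381; adjusted p = 0.866 with an estimated correlation). Values of control 1 were lower: its choroid plexus genes lay on average -1.24 and its meningeal genes -1.69 log2 units from the control mean. Other libraries varied too, with meningeal genes at 1.21 in control 4 and 1.15 in cKO 2. Without control 1 the choroid plexus median was 0.46 (camera adjusted p = 0.00245) and the microglia median 0.10 (camera adjusted p = 0.294). The microglia call was also lost without cKO 1 (0.0702), cKO 2 (0.136) or cKO 4 (0.0593). The E13.5 medians of meningeal fibroblasts (0.17, 14 genes), red blood cells (0.29, 10 genes), endothelial cells and pericytes (0.04, 17 genes), hippocampus and cortical hem (0.12, 14 genes), astrocytes (0.09, 11 genes) and Cajal-Retzius cells (0.08, 12 genes) did not pass camera (adjusted p from 0.0746 to 0.613), with 0 members passing over all genes or adjusted over the list alone.

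The remaining lists did not pass camera at E13.5. Of 20 radial glia genes 0 passed over all genes and 2 fell adjusted over the list alone (median -0.04, camera adjusted p = 0.0998), with the intermediate filament genes Vim at 0.02 and Nes at -0.05. Deep-layer neuron genes had a median of -0.08 (16 genes, camera adjusted p = 0.231). Pcp4, a calmodulin-binding peptide gene, rose (0.77, edgeR adjusted p = 0.00237) and the WNT ligand gene Wnt7b fell (-0.38, edgeR adjusted p = 0.0441). In that list 1 rose and 2 fell adjusted over the list alone. Interneuron genes had a median of 0.02 (19 genes), with Dlx1 at 0.00, and ventral forebrain genes of -0.01 (18 genes), with Meis2 at -0.08. Subplate (0.12, 10 genes), oligodendrocyte lineage (0.01, 11 genes), S phase (0.03, 20 genes), G2 and M phase (-0.04, 20 genes), WNT target (0.12, 12 genes), SHH target (-0.05, 8 genes), interferon (0.14, 12 genes) and mitochondrially encoded (0.01, 13 genes) lists likewise had 0 members passing over all genes or adjusted over the list alone. Thalamic genes had a median of -0.02 (10 genes), with Slc17a6 alone passing under both adjustments. Immediate early genes had a median of 0.12 (11 genes, 0 passing over all genes; 2 rose and 1 fell adjusted over the list alone). Of 19 p53 targets, Sesn2, also an ATF4 target (1.49, edgeR adjusted p = 0.00016), and Pmaip1, a BH3-only gene (1.73, edgeR adjusted p = 0.0263), rose. Adjusted over the list alone 4 rose and 2 fell, and the median was 0.01 (camera adjusted p = 0.209). For the ventral forebrain, thalamus and mitochondrially encoded lists the median, the mean and the direction of the test differed in sign.

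The second comparison asks which genes differ in cKO cortex at P0, when most projection neurons are in place. The integrated stress response was again higher. All 15 of 15 members rose (15 adjusted over the list alone), with a median log2 fold change of 1.13. Atf5 rose from 24.8 ± 1.55 to 254 ± 31.0 CPM (SD, n = 4 each; log2 fold change 3.36, SE 0.09) and Trib3 from 0.476 ± 0.0606 to 6.65 ± 0.49 CPM (3.79, SE 0.12). Sesn2, a stress-induced regulator of mTORC1, rose from 8.24 ± 0.832 to 40.0 ± 2.31 CPM (2.28, SE 0.08) and Ddit3, which encodes CHOP, from 9.44 ± 0.405 to 25.6 ± 1.85 CPM (1.44, SE 0.06). The edgeR adjusted p was 1.56e-08, 4.14e-08, 4.14e-08 and 2.49e-07. The list passed camera (adjusted p = 2.19e-48; adjusted p = 0.00405 with an estimated correlation).

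At P0, 6009 of 18318 genes passed edgeR's quasi-likelihood test, 3063 higher and 2946 lower in cKO tissue. By more than 2-fold, 293 rose and 164 fell, and the groups did not overlap for 5935 genes (32.4%, against 2.86% by chance). Besides the stress genes, Gpnmb, a glycoprotein gene of phagocytic cells, rose from 1.30 ± 0.369 to 17.1 ± 5.09 CPM (log2 fold change 3.72, SE 0.25, edgeR adjusted p = 2.59e-06). Spp1, which encodes osteopontin, rose from 8.81 ± 1.88 to 46.5 ± 15.4 CPM (2.40, SE 0.24, edgeR adjusted p = 3.56e-05). Trim66 (3.35), Slc7a3 (2.78) and Chac1 (2.42) rose as at E13.5. H2-T10, a class I histocompatibility gene annotated as a polymorphic pseudogene, had the value 3.48 (SE 0.82, edgeR adjusted p = 0.00824), carried by cKO 8 and cKO 12 (8.69 and 9.63 CPM), and shares sequence with related genes. The desmosomal cadherin gene Dsc3 fell from 6.68 ± 1.26 to 0.886 ± 0.146 CPM (-2.92, SE 0.17, edgeR adjusted p = 1.48e-06). Robo3, a receptor of commissural axons (-2.39), the deubiquitinase gene Usp43 (-2.23), Nwd2 (-2.02), the thyroid hormone-binding protein gene Crym (-1.87) and the neuropeptide gene Nts, for neurotensin (-1.80), fell as well (edgeR adjusted p from 4.14e-08 to 6.15e-05). The muscle genes Myh3 (-3.24) and Acta1 (-2.07) were highest in control 5, with 14 and 46.0 CPM. Without it the values were -1.64 (edgeR adjusted p = 0.000215) and -0.50 (edgeR adjusted p = 0.0145). The Acta1 call was lost under 5 of 13 alternatives. Other named genes lost their call under at least 6 alternatives: Ndnf, Lhx1, Abcc9, Tcf7, Gli1 and Gas1.

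Genes of excitatory cortical neurons fell at P0. Of 16 deep-layer genes 10 fell and 1 rose (12 and 2 adjusted over the list alone). Their median log2 fold change was -0.51 (camera adjusted p = 7.17e-14; adjusted p = 0.00405 with an estimated correlation). Fezf2, the factor that specifies subcerebral projection neurons, fell from 65.3 ± 4.73 to 34.7 ± 0.483 CPM (-0.91, SE 0.05, edgeR adjusted p = 1.29e-06). The transcriptional cofactor gene Ldb2 fell from 104 ± 3.68 to 58.0 ± 2.02 CPM (-0.85) and Rprm, for the cell cycle regulator reprimo, from 128 ± 2.36 to 62.1 ± 5.80 CPM (-1.05). Wnt7b fell as well (-1.01). Of 16 genes of newborn and migrating neurons 10 fell and 1 rose (11 and 1 adjusted over the list alone; camera adjusted p = 2.89e-06; adjusted p = 0.014 with an estimated correlation). Their median was -0.25, and among them were the neurogenic factor genes Neurod6 (-1.0) and Neurod2 (-0.52), the microtubule regulator gene Stmn2 (-0.72) and the neuronal tubulin gene Tubb3 (-0.63). Of 17 upper-layer genes 9 fell and 0 rose (9 and 0 adjusted over the list alone). Their median was -0.37 (camera adjusted p = 1.76e-10; adjusted p = 0.122 with an estimated correlation). Among those that fell were Pou3f1 (-1.35), Dok5 (-1.04) and Mef2c (-0.94). Of 20 synaptic genes 18 fell and 1 rose (19 and 1 adjusted over the list alone). Their median was -0.39 (camera adjusted p = 1.06e-11; adjusted p = 0.105 with an estimated correlation). Slc17a7, the vesicular glutamate transporter gene of cortical excitatory neurons, fell most in the list (99.3 ± 4.33 to 34.6 ± 3.28 CPM; -1.52, SE 0.07, edgeR adjusted p = 2.49e-07). The kinase gene Camk2b (-0.61), the adhesion gene Nlgn1 (-0.56) and the vesicle fusion gene Snap25 (-0.33) fell too. Of 11 subplate genes 6 fell and 2 rose, and as many adjusted over the list alone. Their median was -0.27 (camera adjusted p = 0.00489; adjusted p = 0.093 with an estimated correlation). The nuclear receptor gene Nr4a2 (-1.10), Hs3st4 (-0.78) and the complexin gene Cplx3 (-2.04) fell, while Moxd1 rose (0.99). Mitochondrially encoded genes fell in 12 of 13 (12 adjusted over the list alone), with mt-Atp6 at -0.32, mt-Nd1 at -0.33, mt-Nd4 at -0.26 and mt-Nd4l at -0.23. Their median was -0.24 (camera adjusted p = 7.71e-05; adjusted p = 0.369 with an estimated correlation), and their share of counts was 3.52% ± 0.118 in controls and 3.19% ± 0.0999 in cKO libraries.

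Microglia and interneuron genes rose in the same P0 libraries, and lists of neighbouring tissue passed at the preset correlation but not at an estimated one. Of 16 microglia genes 15 rose and 0 fell (15 and 0 adjusted over the list alone). Their median log2 fold change was 1.44 (camera adjusted p = 2.19e-48; adjusted p = 0.00556 with an estimated correlation). Csf1r, the receptor on which microglia depend, rose from 22.4 ± 2.74 to 61.1 ± 2.65 CPM (1.45, SE 0.08, edgeR adjusted p = 8.92e-07). Laptm5 rose from 15.7 to 42.9 CPM (1.45) and Fcrls from 6.40 to 21.9 (1.78). Interneuron genes rose in 17 of 19 and fell in 1, and as many adjusted over the list alone. Their median was 0.64 (camera adjusted p = 8.46e-19; adjusted p = 0.0167 with an estimated correlation). The GABA-synthesis gene Gad2 rose (94.3 ± 2.5 to 169 ± 9.68 CPM; 0.84, SE 0.05, edgeR adjusted p = 1.29e-06), as did the neuregulin receptor gene Erbb4 (0.92) and the transcription factor gene Lhx6 (0.61). Ventral forebrain and striatum genes rose in 13 of 18 (14 rose and 1 fell adjusted over the list alone), with the neuropeptide genes Tac1 (0.85) and Penk (0.74) and the transcription factor genes Six3 (1.01) and Zfp503 (0.82). Their median was 0.69 (camera adjusted p = 1.16e-06; adjusted p = 0.369 with an estimated correlation). Choroid plexus genes rose in 12 of 13 (12 adjusted over the list alone), with Kcne2 (1.24), Cldn2 (1.12), Kl (0.46) and Enpp2 (0.45). Their median was 1.10 (camera adjusted p = 5.31e-05; adjusted p = 0.386 with an estimated correlation). In control 5 these genes lay on average -0.67 log2 units from the control mean, and without it the median was 0.83. Meningeal genes rose in 6 of 14 (7 rose and 1 fell adjusted over the list alone), with Ogn (0.71), Col1a1 (0.51), Col1a2 (0.43) and Igf2 (0.36). Their median was 0.18 (camera adjusted p = 0.0219; adjusted p = 0.457 with an estimated correlation; 0.0548 without control 13). With all 4 groups in 1 fit the calls of Ogn, Col1a1, Col1a2, Igf2, Kcne2, Enpp2 and Kl were lost (edgeR adjusted p = 0.0637, 0.521, 0.584, 0.416, 0.0535, 0.137 and 0.0738).

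Radial glia and cell cycle lists passed upwards at P0 at the preset correlation but not at an estimated one. Of 20 radial glia genes 11 rose and 2 fell (11 and 3 adjusted over the list alone). Their median was 0.25 (camera adjusted p = 0.00431; adjusted p = 0.386 with an estimated correlation). The stem cell factor Sox2 rose from 68.4 ± 4.38 to 111 ± 8.55 CPM (log2 fold change 0.70, SE 0.07, edgeR adjusted p = 2.41e-05), with Id4 at 0.69 and Notch2 at 0.58. Emx1, whose locus drives Cre, fell. Intermediate progenitor genes rose in 7 of 13 and fell in 3, and as many adjusted over the list alone, without passing as a list (median 0.26, camera adjusted p = 0.0519). Eomes rose from 17.3 ± 1.44 to 30.2 ± 1.25 CPM (0.81, SE 0.06, edgeR adjusted p = 6.43e-06). The proneural gene Neurog2 rose by 0.81 and the neuropeptide gene Tac2 by 0.93, while the somatostatin receptor gene Sstr2 fell (-0.46). The list passed without control 4, cKO 7 or cKO 12 (camera adjusted p = 0.0357, 0.0251 and 0.0393). Of 20 S phase genes 16 rose (18 adjusted over the list alone), among them the helicase genes Mcm3 (0.85) and Mcm2 (0.80), Cdt1 (0.75) and Uhrf1 (0.71). Their median was 0.34 (camera adjusted p = 3.33e-07; adjusted p = 0.369 with an estimated correlation). Of 20 G2 and M phase genes 15 rose (16 adjusted over the list alone), among them Top2a (0.50), Ccnb1 (0.47), Birc5 (0.47) and Mki67 (0.45). Their median was 0.31 (camera adjusted p = 2.69e-05; adjusted p = 0.369 with an estimated correlation). Of 20 p53 targets 5 rose and 2 fell (7 and 3 adjusted over the list alone). The median was 0.16, or 0.09 without control 13 (camera adjusted p = 0.0152; adjusted p = 0.369 with an estimated correlation). Sesn2, the proapoptotic gene Bbc3 (0.47) and Perp (0.37; edgeR adjusted p = 0.0531 with all 4 groups in 1 fit) rose, and the polo-like kinase gene Plk2 fell (-0.37).

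The other P0 lists did not pass camera. NURF and ISWI subunits had a median of 0.10 (14 genes, 6 rose and 2 fell, and as many adjusted over the list alone, camera adjusted p = 0.207), with Hmgxb4 (0.59) and Baz2b (0.38) higher and Smarca1 (-0.37) and Bptf lower. Endothelial and pericyte genes had a median of 0.03 (18 genes, 3 rose and 1 fell; 2 and 1 adjusted over the list alone), with Vtn (0.48), Slco1a4 (0.82) and Abcc9 (0.36) higher and Mfsd2a (-0.46) lower. Red blood cell genes had a median of -0.29 (7 genes, 1 fell; 0 adjusted over the list alone). Astrocyte genes had a median of 0.12 (13 genes, 5 rose and 2 fell, and as many adjusted over the list alone). The lipoprotein gene Apoe rose from 250 ± 33.9 to 556 ± 21.2 CPM (1.15, edgeR adjusted p = 4.91e-06) and the intermediate filament gene Gfap by 0.83. By contrast, Sparcl1 (-0.37) and Aldh1l1 (-0.30) fell. Oligodendrocyte lineage genes had a median of -0.04 (12 genes, 3 rose and 2 fell; 4 and 4 adjusted over the list alone), with Bcas1 (0.99) higher and Cspg4 (-0.51) and Mbp (-0.16) lower. Hippocampal and hem genes (median 0.25, 14 genes) rose in 6 and fell in 2 (7 and 2 adjusted over the list alone). Among them were Prox1 (0.64), Zic5 (0.53) and Wnt5a (0.43) higher and Grik4 (-0.74) lower. Thalamic genes (0.33, 12 genes) rose in 5 (5 rose and 1 fell adjusted over the list alone), with Zic1 (0.38), Tcf7l2 (0.38), Foxp2 (0.34) and Rora (0.22). Cajal-Retzius genes (0.16, 12 genes) rose in 2 and fell in 1 (1 and 0 adjusted over the list alone): Cacna2d2 (0.42), Lhx1 (0.49) and Ndnf (-0.22). Of 14 interferon genes Ifit3 rose (0.88; 1 adjusted over the list alone; median 0.18). Of 13 immediate early genes Npas4 rose (0.91) and Egr1 (-0.77) and Egr2 (-0.78) fell, and as many adjusted over the list alone (median -0.02). WNT targets (median -0.02, 14 genes) rose in 3 and fell in 1 (4 and 1 adjusted over the list alone): Nkd1 (0.39), Axin2 (0.25), Tnfrsf19 (0.24) and Tcf7 (-0.20). SHH targets (-0.05, 8 genes) rose in 2 and fell in 2 (3 and 2 adjusted over the list alone): Ptch1 (0.23), Gas1 (0.14), Boc (-0.36) and Gli1 (-0.50). Axon guidance genes (-0.01, 20 genes) rose in 5 and fell in 6, and as many adjusted over the list alone: Robo3, Efna5 (-0.69) and Sema3c (-0.29) fell and Ntn1 (0.63) rose. The calls of Zic1, Rora, Vtn, Slco1a4, Mbp, Tnfrsf19 and Ptch1 were lost with all 4 groups in 1 fit (edgeR adjusted p = 0.0774, 0.086, 0.205, 0.161, 0.125, 0.0913 and 0.0541), and those of Rora and Mbp with length offsets too (0.483 and 0.293). Without control 3 the call of Rora was lost (0.0503), and without cKO 11 or cKO 12 that of Boc (0.0538 and 0.0551). For the WNT and oligodendrocyte lists the median differed in sign from the mean and the test.

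**Figure D2:**
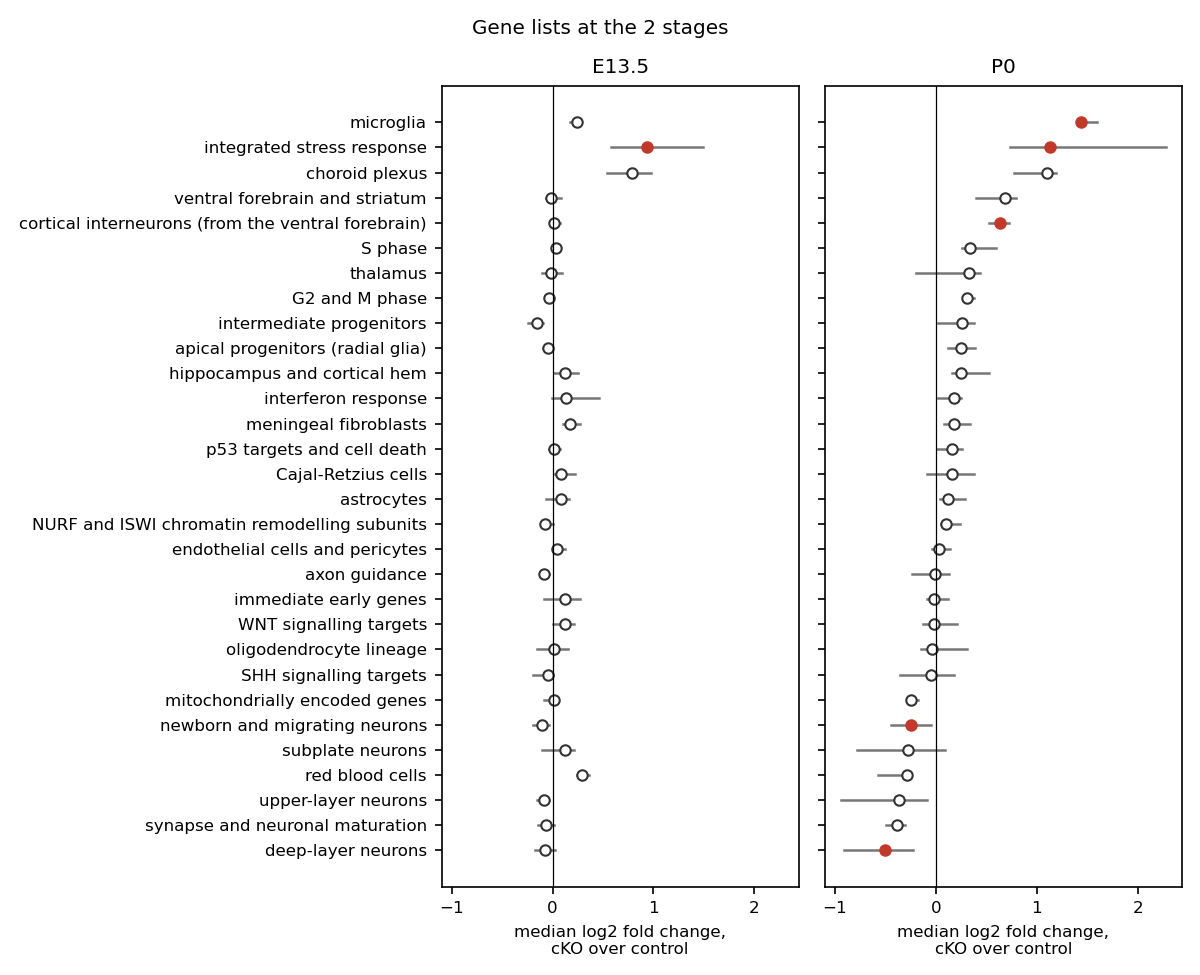
Median log2 fold change (cKO over control) of the members of each of the 30 gene lists at E13.5 and P0, with lines for the 95% bootstrap interval over member genes and filled points for lists that passed camera with an estimated correlation. The integrated stress response lies at 0.94 and 1.13, while microglia genes lie at 0.24 and 1.44 and deep-layer genes at -0.08 and -0.51.

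The third comparison asks whether genes that changed at E13.5 also changed at P0, and where the effect differed. The shared genes include Trib3, Chac1, Atf5, Trim66 and Slc7a3, which rose at both stages, and Bptf and Smarca1, which fell at both. Of the 132 genes higher at E13.5, 105 were also higher at P0, where independent lists would share 24.8 (odds ratio 17.4, 95% confidence interval 11.3 to 27.7, Fisher's exact test, adjusted p = 2.35e-51). Of the 155 lower genes, 97 were also lower at P0, against 29.1 for independent lists (odds ratio 7.45, interval 5.31 to 10.5, Fisher's exact test, adjusted p = 3.65e-33). With the DESeq2 Wald test 172 higher and 259 lower genes were shared. Opposite calls were rare: 3 genes rose at E13.5 and were lower at P0 (Slc35f2, Exoc6 and Pus7l) and 2 fell at E13.5 and were higher at P0 (Rgs16 and Celsr1), all 5 named after their values were seen. Fold changes had the same sign at both stages for 259 of the 287 genes called at E13.5 (90.2%); across all 14950 genes the Spearman correlation was 0.329, and genes are not independent replicates.

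The genotype effect itself differed between stages for 2239 of 14950 genes (edgeR interaction test), 1105 with a higher and 1134 with a lower log2 fold change at P0. Within the naming rule's limits on level and symbol, the largest positive differences were in Myo1f, a myosin gene of leukocytes (2.44, SE 0.31, edgeR adjusted p = 9.94e-05), Spp1 (2.37), the transporter gene Abcc3 (2.33) and Cd180, a Toll-like receptor homologue of immune cells (2.01). Ppp1ccb had a difference of 2.40 (SE 0.68), but it is a near-identical copy of Ppp1cc. Within the same limits the largest negative differences were in Robo3 (-2.42, SE 0.31, edgeR adjusted p = 0.000115), Crym (-2.08), the neurotrophin gene Ntf3 (-2.08), Nwd2 (-2.0) and Usp43 (-1.77). Among the lists, 14 passed camera for the difference and 2 of them passed with an estimated correlation: microglia (median difference 1.29; adjusted p = 0.0442 with an estimated correlation) and interneurons (0.64; adjusted p = 0.0442 with an estimated correlation). For choroid plexus genes the difference did not pass the test (0.25, camera adjusted p = 0.822). The call of Ppp1ccb was lost in 3 fits that left out a library, and each stage was quantified by another tool, so a gene-specific bias that acts on 1 genotype cannot be separated from stage.

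**Figure D3:**
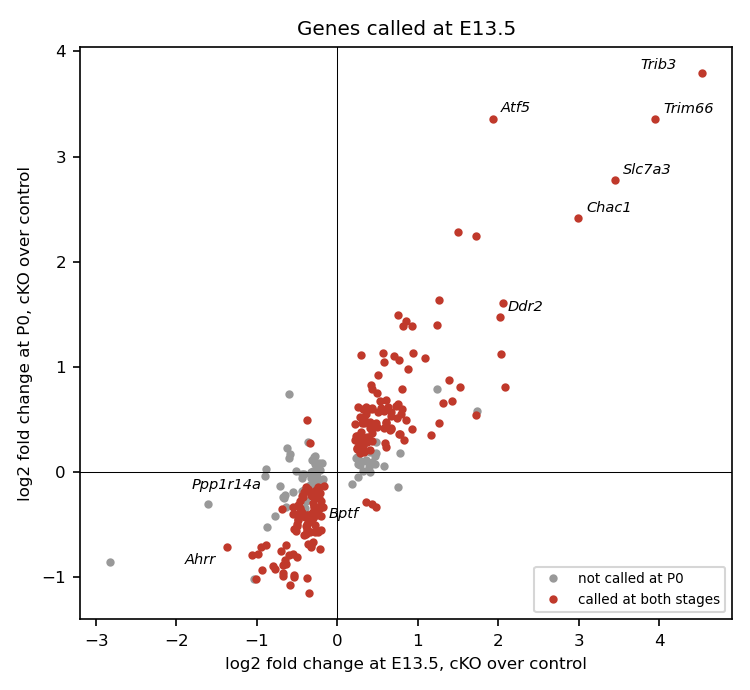
Log2 fold change (cKO over control) at P0 against that at E13.5 for 285 genes called at E13.5, each a point; 207 also called at P0 are in red and the other 78 in grey. Lenep and Gm3298, with no counts in a whole group at E13.5, are left out; most points lie in the quadrants where both changes have the same sign, with Trib3 at 4.54 and 3.79.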

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

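The test of a lower share of excitatory cells, and the splits that count lists with an estimated correlation, were chosen only after the results they bear on had been seen; the latter were added once the splits at the preset correlation had not excluded chance.

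Integrated stress response genes were higher in cKO libraries at both stages, by a median log2 fold change of 0.94 and 1.13. The test of stress during dissection assumed that it would raise immediate early genes by as much. The upper end of the 95% bootstrap interval of their median was 0.274 at E13.5 and 0.123 at P0, below the lower ends of the stress list, 0.58 and 0.74. On the spread over genes alone, this argues against stress of that kind. Dissection stress that raises immediate early genes less is not decided by this test. Unequal sex of the animals and a single library are argued against as well: with a Ddx3y covariate the list's median was at least 1.01 times its value without, and leaving out any of the 16 libraries left at least 0.948 of it. A candidate explanation is a response of Emx1-lineage cells to the loss of BPTF, as a hypothesis. An effect of Cre itself stays open and untested, because Cre was present in cKO samples alone.

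Microglia genes were higher in P0 cKO libraries, by a median log2 fold change of 1.44. A lower share of excitatory cells alone would raise the markers of other cell types alike, but the lower end of the microglia interval, 1.4, lay above the upper ends for interneurons (0.73) and for endothelial cells and pericytes (0.14). Blood and meninges carried along are argued against as the whole cause too, on the spread over genes alone. The red blood cell list (7 genes) did not itself pass camera (adjusted p = 0.292). The upper ends of the intervals of the red blood cell and meningeal fibroblast lists were -0.252 and 0.338. Choroid plexus genes had a median of 1.10 (interval 0.77 to 1.19; 0.83 without control 5), nearer to microglia than those lists, so choroid plexus carried along stays open as a source of part of the rise. A candidate explanation is more microglia, or more of these transcripts per microglial cell, in cKO tissue; bulk tissue does not separate these, and a lower share of excitatory cells could still account for part of the rise.

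Upper-layer and synaptic genes were lower in P0 cKO libraries, by medians of -0.37 and -0.39. The trend of fold change on mean effective transcript length (exonic length had been planned) and on GC content of the longest transcript was removed. This left at least 0.936 of both medians, which argues against such a bias as the whole cause, although that trend took up only 0.611% of the deviance over all genes. More ventral forebrain tissue in the cKO dissections stays open: the lower end of the interval of ventral forebrain and striatum genes was 0.396, above 0 as that explanation needs. Of these 18 genes 13 rose and 0 fell over all genes. Among those that did not pass were Drd1, Foxp1 and Meis2, at -0.37, 0.01 and 0.22 (adjusted over the list alone, Drd1 fell and Meis2 rose). Fewer excitatory neurons, and lower expression within them, may each contribute, and neither was tested.

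Other splits of the libraries argue against chance for the counts of genes: 1 of 35 splits, the real one, gave as many as 287 genes at E13.5 (highest other 23) and as many as 6009 at P0 (highest other 315). That is the smallest share 35 splits can give, and every other split mixes the genotypes, which adds the genotype effect to the spread and can lower its calls. The 315 genes came from a split that placed cKO 7 with 3 controls. That split kept part of the genotype difference, so 315 is not a ceiling for chance alone. The next highest at P0 was 6. Other splits that placed cKO 7 with 3 controls gave 0 genes, so these counts do not settle whether cKO 7 resembles the controls. The splits do not argue against chance for the number of lists called at the preset correlation: 27 of 35 splits gave at least 9 lists at E13.5 (highest other 19) and 8 of 35 gave at least 16 at P0 (highest other 19). With an estimated correlation, 1 of 35 splits at each stage gave as many as the real 1 list at E13.5 (highest other 0) and the real 5 lists at P0 (highest other 1). This argues against chance without excluding it, and at E13.5 it rests on 1 list. For the difference between stages, 3 of 100 splits gave as many as 2239 genes. The other 2 kept the P0 genotypes (2253 and 2321 genes) and the remaining 97 gave at most 55, so the count follows the P0 genotypes and these splits do not test whether the effect differs between stages.

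In 9 of 204 groups tested, 1 library lay far from the others, where chance gives about 10.2. These were Zkscan4 at 9.57 CPM in E13.5 control 1, Myh3 at 14 and Acta1 at 46.0 CPM in P0 control 5, and the share of the 20 most abundant genes at 6.19% in E13.5 cKO 1. As mean log2 differences of lists from the control mean, they were subplate genes at -0.055 in P0 control 13, microglia genes at 1.07 and mitochondrially encoded genes at -0.34 in P0 cKO 7, astrocyte genes at -0.15 in P0 control 5 and interferon genes at 0.18 in E13.5 control 4.

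The genotype effect differed between stages, by edgeR's interaction test, for 10 named genes, as differences of log2 fold changes (P0 minus E13.5): Myo1f 2.44, Ppp1ccb 2.40, Spp1 2.37, Abcc3 2.33, Cd180 2.01, Usp43 -1.77, Nwd2 -2.0, Ntf3 -2.08, Crym -2.08 and Robo3 -2.42. Of the 14 lists that differed by camera, those with higher values at P0 had median differences of 1.29 (microglia), 0.66 (ventral forebrain and striatum), 0.64 (interneurons), 0.36 (G2 and M phase), 0.35 (S phase), 0.34 (intermediate progenitors), 0.30 (radial glia), 0.18 (NURF and ISWI subunits) and 0.16 (integrated stress response). Those with lower values at P0 had medians of -0.54 (deep-layer neurons), -0.36 (synapse), -0.24 (mitochondrially encoded), -0.20 (upper-layer neurons) and -0.063 (newborn and migrating neurons). With an estimated correlation, 2 of the 14 passed, microglia and interneurons.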

How the results depend on the processing

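The Ddx3y covariate was chosen after seeing the data; the planned Xist covariate was not run. Called values kept their sign, except the E13.5 synapse median, 0.04 without control 1 and 0.01 without cKO 2 (neither called). At E13.5 the 287 calls (132 higher, 155 lower) moved to 157 (79, 78) with transcript-length offsets, 181 (94, 87) with the Ddx3y covariate, 695 (266, 429) with the DESeq2 Wald test and 579 (250, 329) with all 4 groups in 1 fit; of the 287, 147, 174, 285 and 268 were kept. Leaving out each library gave 156 to 216 calls (78 to 101 higher, 77 to 127 lower) and 7 to 15 lists against 9. The causes were not tested, beyond fewer samples when a library is left out. With DESeq2 38.3% of E13.5 calls were higher, against 46.0%. Lists called with an estimated correlation fell to 1 at E13.5 and 5 at P0 (against 16), and fry called 1 and 21. Genes shared by both stages moved from 202 to 431 with DESeq2 (172 higher, 259 lower). At P0 leaving out a library gave 4663 to 6589 calls (2332 to 3303 higher, 2331 to 3286 lower) and 15 to 17 lists, and for the stage difference 1626 to 2588. Among named genes and differences, 59 comparisons at E13.5, 79 at P0 and 3 between stages lost a call, and 4 at E13.5 gained one; among lists, leaving aside the estimated correlation and fry, 17 and 1 lost and 25 and 5 gained a call.

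The E13.5 groups share the numbers 1 to 4, which the labels do not tie to litters. Deviations of same-numbered libraries correlated at 0.055, 0.204, 0.048 and -0.116, and number 2 alone correlated best with its own. These correlations do not settle whether same-numbered libraries share a litter or a batch, and the main fit did not pair them. With the replicate number as a block, 159 genes (79 higher, 80 lower) and 12 lists were called. The lower depth at E13.5 limits genes with low counts there.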

Other observations

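The gene groups below were put together after the results had been seen, so tests of them as sets decide nothing and are given only where they did not pass; the tests of endoplasmic reticulum chaperones and of mitochondrial synthetases were set before the values of those genes were seen.

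Of 10 genes of a phagocytic microglial state 9 rose at P0 (9 adjusted over the list alone), with a median log2 fold change of 2.35. Besides Gpnmb and Spp1, which the naming rule had already picked, the integrin gene Itgax rose by 3.09, the cystatin gene Cst7 by 2.57, the pattern receptor gene Clec7a by 2.50, the lysozyme gene Lyz2 by 2.29 and the galectin gene Lgals3 by 1.74. Lpl stood at -0.15 at P0 (edgeR adjusted p = 0.136) and rose at E13.5 (0.75). At E13.5, 5 of the genes were measured and Lpl alone passed.

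Genes of the clustered protocadherins on chromosome 18, cell-surface proteins that give neurons individual identities, fell more often than they rose. At E13.5, 6 of 56 fell and 1 rose (19 fell and 1 rose adjusted over the list alone; median -0.31, camera p = 0.0898 with an estimated correlation). At P0, 33 of 57 fell and 8 rose (35 and 10 adjusted over the list alone; median -0.40). Members share sequence and 3' exons, so values of single genes are uncertain.

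The genes that encode cytosolic aminoacyl-tRNA synthetases, many of them ATF4 targets, rose more often than they fell. At E13.5, 10 of 20 rose and 0 fell (12 rose adjusted over the list alone; median 0.27), with Cars at 0.80 and Nars at 0.49. At P0, 12 rose and Wars fell (-0.19; 13 and 1 adjusted over the list alone; median 0.34, camera p = 0.164 with an estimated correlation). As a hypothesis, the rise could be part of the ATF4 program and spare the mitochondrial synthetases. The upper end of the 95% bootstrap interval of the mitochondrial median, 0.122 at P0, overlapped the cytosolic interval (0.03 to 0.48), and the intervals overlapped at E13.5 too (0.03 to 0.10 and 0.07 to 0.36). The groups were thus not separated at either stage, although 0 of 17 mitochondrial genes passed at E13.5 and 2 at P0 (0 and 1 adjusted over the list alone). A second hypothesis, that the stress response runs through the unfolded protein response of the endoplasmic reticulum, predicted that chaperone genes of that compartment rise by as much. They did not: their interval at P0 was 0.03 to 0.193, above 0 but below the lower end of the stress list (0.74). At E13.5 its upper end was 0.02, below 0.58. Of 14 chaperone genes 1 was higher at E13.5 and 3 at P0, and as many adjusted over the list alone. The test asks only whether chaperone genes rise by as much as the stress list, so a smaller rise does not decide whether that route takes part.

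All 10 skeletal muscle genes measured at P0 had lower values in cKO libraries (median -2.15, camera p = 0.575 with an estimated correlation), and 4 passed the test (5 adjusted over the list alone). Control 5 had the highest value of all 10, with 14 CPM of Myh3 and 46.0 of Acta1, and without it Myh3 stood at -1.64 and Acta1 at -0.50.

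Some values stood apart by library. Gm10260 measured 76.9 and 78.4 CPM in P0 cKO 8 and cKO 12 and 4.86 in cKO 11, and H2-T10 measured 8.69 and 9.63 CPM in the same pair. At E13.5, Lenep measured 1.05 to 3.0 CPM in controls and had no counts in the 4 cKO libraries, and Gm3298 had no counts in the 4 controls and 1.12 to 1.85 CPM in cKO libraries. The Y-linked gene Ddx3y measured at most 1.10 CPM in E13.5 control 3 and cKO 1 and 2 and in P0 control 4 and cKO 7, and 4.96 CPM in P0 cKO 12, where Eif2s3y measured 4.16. A small admixture from another library could give so low a signal and was not tested; the 4663 genes that passed at P0 without cKO 12 do not bear on it, since 4718 passed without cKO 8. In the other libraries Ddx3y measured 56.5 to 60.3 CPM at E13.5 and 85.1 to 107 CPM at P0.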
